A study of Homo sapiens with 16 samples.

How the data were processed

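RNA from 16 samples of HBL-1 cells was measured on Illumina bead arrays, with 2 replicates in each of 8 groups: with or without doxycycline at 24, 48, 72 and 96 h. Samples were grouped by their titles, and per the labels the series consists of 8 pairs. The deposited value table holds 47309 probes on the log2 scale. That scale was found from its values, which run from 3.74 to 15.99; the authors' normalization, background correction and any centring of these log2 values are not given in the sources used here. The bead files hold the intensity of each single bead, per the file headers, with its code and position and with no probe names, and no further step by the authors is stated. Some bead intensities are not above 0, between 19 and 289 per array.

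The table medians of the columns as named were 5.023, 5.069, 5.06, 5.054, 5.058, 5.061, 5.049 and 5.026 for the induced arrays, replicate 1 before replicate 2 at each time from 24 to 96 h. For the uninduced arrays in the same order they were 5.042, 5.043, 5.053, 5.017, 5.04, 5.054, 5.052 and 5.039. The bead files had log2 medians of 6.71 to 7.22, so the table does not hold plain log2 bead intensities. In all, 454 values of the table, over 209 probes, are missing, always on both arrays of a pair.

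The direction of the table was found from the bead files. Beads beyond 3 median absolute deviations of their code were left out (1.18% to 1.90% of an array), and the mean of log2 intensity was taken per code. Probes with a mean above 8 were matched to codes above 8.5, within 500 ranks of signal, by the correlation of the 8 pair means, with a least correlation of 0.95. The match gave 8360 probes, and within-pair differences of table and bead files were then correlated across them. In simulated data with 3 exchanged pairs this step matched 86.5% of 6545 probes rightly and gave the right direction for 8 of 8 pairs. The correlations for replicates 1 and 2 were -0.876 and -0.935 at 24 h, -0.885 and -0.871 at 48 h, -0.905 and -0.897 at 72 h, and -0.911 and -0.919 at 96 h. Probe profiles over the 16 arrays had a median best correlation with bead codes of 0.851 with the columns as named and 0.965 with the columns exchanged within pairs. The columns were therefore exchanged within all 8 pairs. The labels of the bead files and the column names disagree, and which of them is right stays unknown.

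Probe names came from the platform annotation: 30108 probes had 1 gene symbol, 8 had several and 17193 were not named here. Of the named probes 30069 were found in a gene table of assembly GRCh38.p14, used for symbols only, and 0 symbols changed. No genome build is named in the files, so no coordinates are given. The upper 50% of the probes by mean signal was kept (median 5.02), and the brightest probe stood for each gene, which left 12463 genes. The table was used without further normalization, since its columns have like medians.

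Differences were tested on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with the pair as a block, and p-values were adjusted by the Benjamini-Hochberg method. The tests were 1 common effect of induction, an effect at each time, a linear trend of the effect in hours and, over the 8 uninduced arrays with the replicate number as a block, a trend with time. The pairing comes from the series' design text. At each time, the deviations of same-numbered arrays from their group means correlated by 0.51, 0.54, 0.69 and 0.54 across genes. Both arrays of a pair shared a BeadChip, and the other pair of that time lay on a different one. A difference between BeadChips alone could give such correlations, so they cannot show that the samples were paired. Any 2 arrays correlated between 0.9703 and 0.9933, and no 2 arrays held the same values. For NFKBIZ and the means of lists, exact sign-flip permutation tests over the 8 pairs were used, and exact permutations of the times (2520 arrangements) for the trends of list means. The 24 gene lists, with 448 of 535 distinct genes tested, were compared with all other genes by camera with a preset correlation of 0.01. Members of a list called measured are those with a named probe above the filter on dim probes. Camera with an estimated correlation and fry, which asks only whether the genes of a list move one way, were alternatives.

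The comparisons and their tests, the samples, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The check of the column direction, 4 alternatives that are named with their effects, and some tests of explanations were chosen after. The rule names NFKBIZ and, over all times, up to 12 genes in each direction with the largest change among those with adjusted p under 0.05 and 8 differences of one sign. At each time it names up to 4 genes in each direction with adjusted p under 0.05 and both pairs of one sign, for the trends up to 5 with adjusted p under 0.05, and for each list described up to 4 members with the smallest p. Genes with no symbol, several symbols or a placeholder name were skipped.

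The fits were tested on simulated data with the real genes' means and spreads, in which 200 of 12463 genes were changed. The first simulation held changes of 0.5 and 1 on the log2 scale. There the common effect recovered 58% and 98% of them, with 6 other genes called, and 29% and 84% without the block. At single times it recovered 0% of the changes of 1 at 24, 48 and 96 h and 1% at 72 h. The second simulation was added after this was seen and also held 60 genes with changes of 2. There the common effect recovered 58.75%, 96.67% and 100% of changes of 0.5, 1 and 2, with 8 other genes called. At single times it recovered 33.33% to 43.33% of the changes of 1, since more strongly changed genes ease the adjusted threshold for all. Slopes of 0.5 per day in uninduced cells were recovered for 67% and 75% of genes in the first and second simulation. Camera called each of 2 lists shifted by 0.1, with 0 other lists. The simulated noise was drawn for each gene on its own, so genes of a list were not correlated. In the real data the estimated correlation was 0.25 for interferon and 0.071 for S-phase genes. The simulation therefore cannot tell how often camera calls a list falsely in the real data. Bead files were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots made with matplotlib 3.10.9.

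An induced array always lay in the section after its uninduced partner on the same BeadChip. All arrays of replicate 1 shared 1 BeadChip, and those of replicate 2 lay on 3. Alternatives covered the source of the values, the scaling between arrays, the filter on dim probes, the block, the variance model, array weights, each pair or replicate left out, the probes of a gene, the thresholds and the set test.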

Results

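The measurements came from HBL-1, an established human cell line of the activated B-cell-like (ABC) class of diffuse large B-cell lymphoma (DLBCL). The cells carried a hairpin RNA against NFKBIZ that doxycycline switches on. NFKBIZ encodes IkB-zeta, a nuclear member of the IkB family that binds NF-kB subunits and alters the transcription of their target genes. 16 Illumina expression arrays covered 8 groups of 2 replicates: induced cells, given doxycycline, and uninduced cells, at 24, 48, 72 and 96 h. Each induced array was set against the uninduced array of the same time and replicate number, which gave 8 pairs. An array held between 945659 and 1069939 beads, with a median of 19 to 22 beads per bead code, and the number of arrays limits the precision. The labels do not say that replicates, or the times of a replicate, came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical. If the times of a replicate shared a culture, the 8 pairs would not be independent and the p-values could be too small. This holds for the limma fits and for the exact permutation tests. Arrays of a non-targeting hairpin, or of doxycycline alone, were not analysed here.

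The first comparison asked how far the hairpin lowered its own target. By the direction of the bead files, the brighter NFKBIZ probe had a mean log2 signal of 13.32 in uninduced and 12.87 in induced arrays. The mean difference was -0.46 ± 0.21 (SD, n = 8 pairs), or 72.9% of the uninduced level (with the columns as named, 1.37-fold the uninduced level), and NFKBIZ was lower in 8 of 8 pairs. An exact sign-flip permutation test of the 8 differences gave p = 0.00781 (two-sided), the smallest that 8 pairs allow. The test takes the 8 differences as independent, which the labels do not establish. In limma the adjusted p was 0.0572, so NFKBIZ missed the threshold of 0.05 over all genes tested. The dimmer NFKBIZ probe differed by -0.645 ± 0.48 (SD, n = 8 pairs) and was lower in 7 of 8 pairs (exact permutation p = 0.0156; limma adjusted p = 0.0916 among all named probes). The mean difference of the brighter probe was -0.33 at 24 h, -0.505 at 48 h, -0.33 at 72 h and -0.65 at 96 h. At 24 h the signal of the brighter probe went from 13.19 to 12.67 in replicate 1 and from 12.98 to 12.84 in replicate 2. The corresponding values at 48 h were 13.32 and 12.74 in replicate 1, and 13.19 and 12.76 in replicate 2. At 72 h they were 13.505 and 13.06, then 13.09 and 12.87. At 96 h they were 13.45 and 12.97, then 13.85 and 13.04.

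All signed values rest on a choice between 2 sets of labels that disagree. In the value table, the columns named induced have the higher signal of the brighter NFKBIZ probe in 8 of 8 pairs and of the dimmer probe in 7 of 8, so that NFKBIZ goes against the column names. Setting the table against the bead files of the same arrays, a check made after this was seen, showed that the columns run opposite to the bead files. Bead codes were matched to 8360 probes by the means of the 8 pairs, which carry no direction and were not tied to NFKBIZ. Across these probes, which are not independent replicates, the within-pair differences of table and bead files correlated between -0.94 and -0.87 in all 8 pairs. The direction of the bead files was used throughout, and with the columns as named every difference between induced and uninduced has the opposite sign. The files alone do not settle which labels are right. The pairs, the sizes of the within-pair differences and their p-values do not depend on this choice, but which arrays count as uninduced does.

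**Figure D1:**
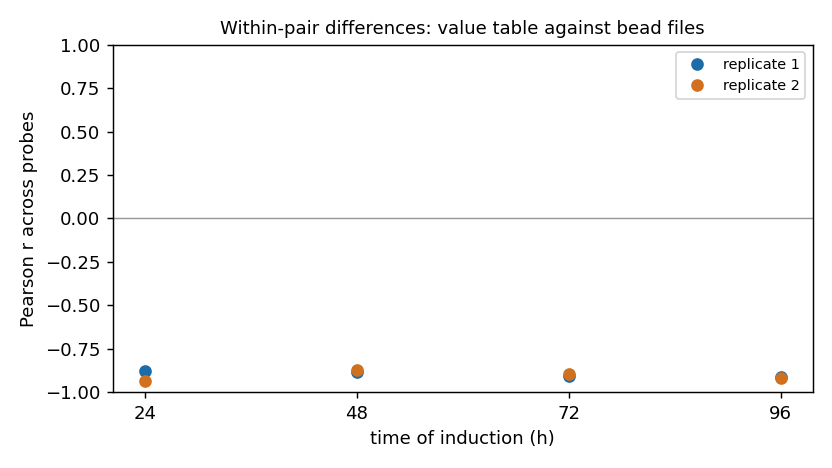
Pearson correlation across 8360 matched probes between the within-pair differences of the value table (columns as named) and of the bead files, by time of induction in hours; each point is 1 pair and colours mark the replicate. All 8 points lie between -0.94 and -0.87.

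**Figure D2:**
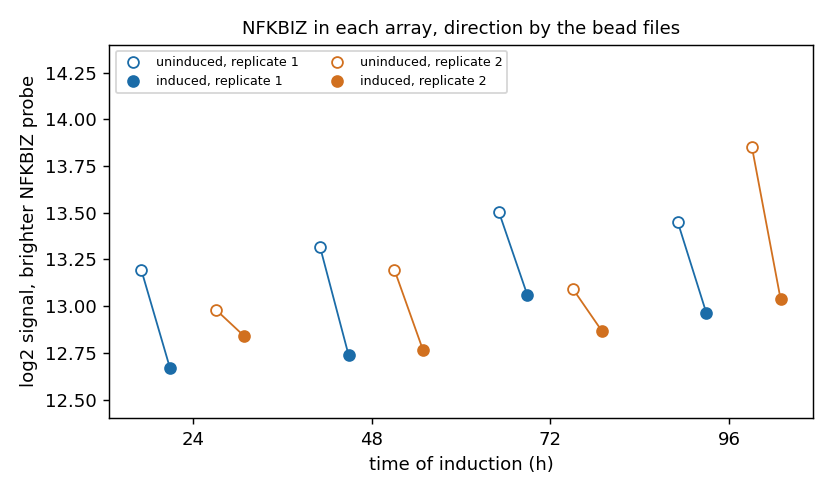
Log2 signal of the brighter NFKBIZ probe in each of the 16 arrays by time of induction in hours, in the direction of the bead files; lines join the uninduced (open) and induced (filled) array of a pair, and the vertical axis does not start at 0. The induced array is lower in 8 of 8 pairs, and with the columns as named it would be higher in all 8.

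The second comparison asked which genes differed between induced and uninduced cells over all 4 times. By the bead-file direction, 17 of 12463 genes passed limma's adjusted p of 0.05, of which 7 fell and 10 rose, each in 8 of 8 pairs. SOCS3, a feedback inhibitor of cytokine signalling through STAT3, fell by 1.21 on the log2 scale (SE 0.17 from limma, adjusted p = 0.0145). P2RX5, an ATP-gated ion channel, fell by 1.02 (SE 0.13, adjusted p = 0.00784). TUBGCP3, a component of the gamma-tubulin complex, fell by 0.90 (SE 0.10, adjusted p = 0.00654), and LRRC32, a receptor that docks latent TGF-beta, fell by 0.83 with the same SE and adjusted p. BCL3, which like NFKBIZ encodes a nuclear protein of the IkB family, fell by 0.58 (SE 0.082, adjusted p = 0.0161). RASSF4, a protein with a Ras association domain, fell by 0.61 (adjusted p = 0.049), and its other probe differed by -1.21. A probe annotated to the microRNA gene MIR658, which says nothing of the mature microRNA, fell by 0.70 (adjusted p = 0.028). The second SOCS3 probe differed by 0.16 in the opposite direction and was lower in 3 of 8 pairs, so the fall of SOCS3 rests on 1 of its 2 probes. Both probes were dim, with mean log2 signals of 6.10 for the first and 5.79 for the second.

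Of the 10 genes that rose, 5 were on the list of type I interferon genes fixed before the data were examined. RSAD2, an antiviral enzyme, rose by 1.02 (SE 0.17, adjusted p = 0.0465), IFIT2 by 0.72 (SE 0.10, adjusted p = 0.0189) and IFIT1 by 0.69 (SE 0.10, adjusted p = 0.0213). SAMD9L and XAF1 rose by 0.56 and 0.51 (adjusted p = 0.025 and 0.049). Without the first pair at 72 h none of these 5 interferon genes passed (adjusted p from 0.0851 to 0.126), and without the second none did either (0.0528 to 0.109). Without the first pair at 96 h only IFIT2 passed, without either pair at 48 h or the second at 96 h only IFIT2 and IFIT1, and without the first pair at 24 h all but XAF1. The second probes of IFIT1 and XAF1 differed by 0.66 and 0.65 in the same direction. DDX60L, a helicase-like gene that is not on the list, rose by 0.90 (SE 0.11, adjusted p = 0.00654). Outside the interferon genes, BCO1, a carotene oxygenase, rose by 0.74 (SE 0.088) and SNX29, a sorting nexin, by 0.74 (SE 0.092). COL4A6, a chain of type IV collagen, rose by 0.71, but its 2 other probes, with mean signals of 4.62 and 4.56 below the array medians, differed by only 0.05 and 0.14. TENT5A, a poly(A) polymerase, rose by 0.525 (adjusted p = 0.049). The uninduced signal of BCO1, 5.09, was also close to the array medians of 5.02 to 5.07, so its level is near background. Other genes past the threshold were dim too: RSAD2 had an uninduced signal of 5.915, MIR658 of 6.04, SNX29 of 6.09 and TUBGCP3 of 6.79.

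**Figure D3:**
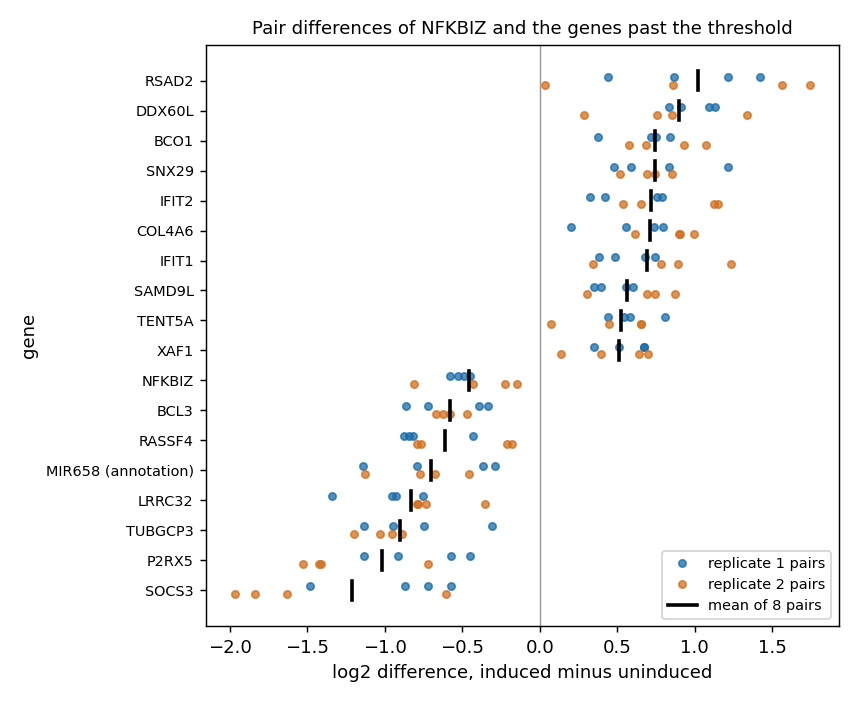
Log2 difference, induced minus uninduced in the direction of the bead files, for NFKBIZ and the 17 genes past the threshold; each point is 1 of 8 pairs, colours mark the replicate, and black bars are means. The means run from -1.21 for SOCS3 to 1.02 for RSAD2, with all 8 pairs of each gene on one side of 0; with the columns as named, every sign turns.

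The count of 17 depends on the fit. Without the pair as a block, limma called 0 genes, with the BeadChip as the block 35, with an intensity trend in the variance 190, and among the upper 25% of probes 156. Summaries of the bead files, which carry no gene names, gave 587 codes. With replicate 1 alone, on 1 BeadChip, and with replicate 2 alone, on 3 BeadChips, the count was 0. Leaving out the first or second pair at 72 h left 6 and 8 genes, the first pair at 48 h left 11, and the first pair at 96 h left 10. P2RX5, TUBGCP3, LRRC32, DDX60L, BCO1 and SNX29 passed without each of the 8 pairs in turn. Of these, BCO1 was near background, and SNX29 and TUBGCP3 were dim. At an unadjusted p under 0.05 there were 1736 genes, and 408 genes had the same sign in all 8 pairs, 3.27% against the 0.78% that chance gives. Across genes, the differences of any 2 pairs correlated between -0.08 and 0.3, with a median of 0.1.

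Genes of the type I interferon response rose as a group. By the bead-file direction, 5 of the 33 measured members rose, none fell and 28 did not pass; adjusted over the list alone, 24 passed, all higher. The list mean was 0.39 ± 0.17 (SD, n = 8 pairs) and was higher in 8 of 8 pairs (limma camera, adjusted p = 1.11e-23). With an estimated correlation the adjusted p was 0.101, so this call does not hold there. With arrays exchanged in 4 of the 8 pairs, which cancels a common effect, camera with the preset correlation still called 1 list in 13 of 28 such splits. The mean was 0.24 at 24 h, 0.27 at 48 h, 0.45 at 72 h and 0.58 at 96 h. The linear trend over the times was 0.12 per day (exact permutation p = 0.00794, adjusted over 24 lists 0.162).

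Antigen presentation genes had a higher mean in the induced arrays by the bead-file direction, 0.11 ± 0.13 (SD, n = 8 pairs), in 7 of 8 pairs (camera adjusted p = 0.0349). The adjusted p was 0.356 with an estimated correlation, and the exact permutation test of the mean gave 0.0625 (adjusted over 24 lists 0.125). Of 19 measured members none passed over all genes, and 3 did when adjusted over the list alone. HLA-DRA, a chain of a class II molecule, differed by 0.46 and its chaperone CD74 by 0.38. HLA-DMB, which helps load peptides, differed by 0.285 and HLA-DOB by 0.43. The list lost its call without the second pair at 48 h (adjusted p = 0.0663), without the first or second pair at 72 h (0.089 and 0.106), without the first pair at 96 h (0.0509) and without replicate 1 (0.277). It also did so among the upper 25% of probes (0.0514), and over all alternatives its adjusted p ran from 0.00178 to 0.356.

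Genes of IL-6, IL-10 and STAT3 signalling fell as a group by the bead-file direction, with a list mean of -0.17 ± 0.09 (SD, n = 8 pairs) that was lower in 7 of 8 pairs (camera adjusted p = 0.00857). With an estimated correlation the adjusted p was 0.151. The list median was -0.12, and the mean includes the difference of -1.21 from 1 SOCS3 probe. Of 20 measured members 2 fell, SOCS3 and BCL3, and 18 did not pass; adjusted over the list alone, 4 were lower and 1, the kinase gene JAK2 with 0.45, higher. BATF, a transcription factor of activated B cells, differed by -0.46 (adjusted p = 0.0659) and STAT3 itself by -0.40 (adjusted p = 0.145). With replicate 1 alone the list mean was -0.11 and the adjusted p 0.102.

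The study's title places NFKBIZ in NF-kB signalling, and 3 lists address that. Of 14 measured NF-kB subunits and IkB family members, BCL3 fell and 13 did not pass; the list mean was -0.12 ± 0.07 (SD, n = 8 pairs; camera adjusted p = 0.0592). The list passed with fry (adjusted p = 0.0089) and with the exact permutation test of its mean (adjusted over 24 lists 0.0468). The list holds NFKBIZ itself, the target of the hairpin. It shares BCL3 with the list of IL-6, IL-10 and STAT3 signalling. RELA, an NF-kB subunit, differed by -0.53 (adjusted p = 0.085) and was lower in 8 of 8 pairs, while NFKBIE differed by 0.18. Adjusted over the list alone, BCL3, NFKBIZ and RELA passed, all lower. Of 39 NF-kB target genes none passed, and the list mean was -0.03 ± 0.09 (SD, n = 8 pairs; camera adjusted p = 0.546). Adjusted over the list alone 2 were lower: EBI3, a cytokine subunit, differed by -0.32 and GADD45B, a stress sensor, by -0.40. IL2RG differed by 0.355 and CD40 by -0.25. Camera and the list mean ask only for a common direction. A form of fry that counts changes either way gave the NF-kB target genes an adjusted p of 1.61e-05. It gave low values to other lists too, such as plasma-cell genes (0.000121), so it does not single out NF-kB targets. The list of genes known to depend on IkB-zeta in other cell types held 21 genes, of which 9 were tested. The others had no named probe above the filter on dim probes. None passed the threshold, and the list mean was 0.01 ± 0.11 (SD, n = 8 pairs; camera adjusted p = 0.934). Among the measured members IL10 differed by -0.22, EDN1 by 0.33, CXCL8 by -0.29 and IL23A by 0.15. Uninduced signal was low for HAMP (5.046), IL23A (5.201), IL17C (5.396) and EDN1 (5.702), not far above the array medians. It was highest for IL10 (12.58), lower in 7 of 8 pairs, and ZC3H12A (10.57), higher in 5 of 8. The list mean therefore says little about how such genes respond in these cells. By the bead-file direction NFKBIZ mRNA stayed at 72.9% of the uninduced level, and its protein was not measured here. For the NF-kB target list as well, the lack of a common change therefore says little about dependence on NFKBIZ.

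B-cell identity genes did not pass as groups in camera, which compares a list with the other genes, but ABC markers passed tests of the list alone. Marker genes of ABC DLBCL had a mean of -0.08 ± 0.04 (SD, n = 8 pairs) by the bead-file direction and were lower in 8 of 8 pairs, but camera's adjusted p was 0.0505. Fry gave an adjusted p of 0.00306, and the exact permutation test of the list mean 0.00781 (adjusted over 24 lists 0.0375). None of the 22 measured members passed over all genes, and 3 were lower when adjusted over the list alone. These were BATF, STAT3 and CYB5R2, which differed by -0.46, -0.40 and -0.31. PIM1, a kinase, differed by -0.17. BATF, STAT3 and PIM1 are also on the list of IL-6, IL-10 and STAT3 signalling, so the results of both lists are not independent. Germinal-centre markers had a mean of 0.07 (13 measured, camera adjusted p = 0.223), plasma-cell genes 0.02 (17 measured, 0.813) and B-cell receptor signalling genes 0.01 (20 measured, 0.829). No member of these lists passed, over all genes or over its list alone. Examples were the adaptor STAP1 with 0.44, the surface protein SLAMF7 with 0.28 and the inhibitory receptor FCGR2B with 0.23.

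Genes of S phase fell as a group by the bead-file direction. The list mean was -0.18 ± 0.09 (SD, n = 8 pairs), lower in 8 of 8 pairs (camera adjusted p = 1.3e-07), and 30 of 33 measured members were lower. With an estimated correlation the adjusted p was 0.101. No member passed over all genes, and 5 did when adjusted over the list alone, all lower. E2F8, a transcription factor of the cell cycle, differed by -0.48 and RFC2, part of the clamp loader of DNA replication, by -0.54. CHAF1A, a chromatin assembly factor, differed by -0.36 and CDC45, a replication helicase component, by -0.28. The mean was -0.06 at 24 h, -0.21 at 48 h, -0.24 at 72 h and -0.215 at 96 h. The trend over the times gave an exact permutation p of 0.102.

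Genes of mitosis also fell as a group, with a list mean of -0.10 ± 0.11 (SD, n = 8 pairs) that was lower in 6 of 8 pairs (camera adjusted p = 0.0016). The adjusted p was 0.306 with an estimated correlation and 0.257 without replicate 1, and the exact permutation test of the mean gave 0.0547 (adjusted over 24 lists 0.119). None of 34 members passed over all genes, and 2 did when adjusted over the list alone: KIF2C, a mitotic kinesin, differed by -0.30 and the transcription factor FOXM1 by -0.31. MKI67 and CDC20 differed by -0.23 and -0.27. The list mean was 0.06 at 24 h, -0.18 at 48 h, -0.18 at 72 h and -0.10 at 96 h in the direction of the bead files. MYC and ribosome biogenesis genes had a mean of -0.07 ± 0.05 (SD, n = 8 pairs), lower in 8 of 8 pairs, and missed the threshold of camera (27 measured, adjusted p = 0.0505). They passed with fry (adjusted p = 0.0089) and with the exact permutation test of the mean (adjusted over 24 lists 0.0375). Of these BOP1 and MYC passed over the list alone and differed by -0.33 and -0.30; RRP9 differed by -0.20 and FBL by -0.21.

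Genes of the ATF4 pathway, which responds to amino acid shortage and other stress, fell as a group. The list mean was -0.17 ± 0.17 (SD, n = 8 pairs) by the bead-file direction, lower in 8 of 8 pairs (camera adjusted p = 0.000113). With an estimated correlation the adjusted p was 0.306, and without replicate 1 it was 0.271 at a mean of -0.10. None of 26 members passed over all genes, and 2 did over the list alone: PSPH, of serine synthesis, differed by -0.54 and DDIT4, a stress-induced inhibitor of mTOR, by -0.44. PHGDH differed by -0.36 and ATF3 by -0.31. The first pair at 96 h differed most, by -0.53, and the others by -0.26 to -0.01.

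**Figure D4:**
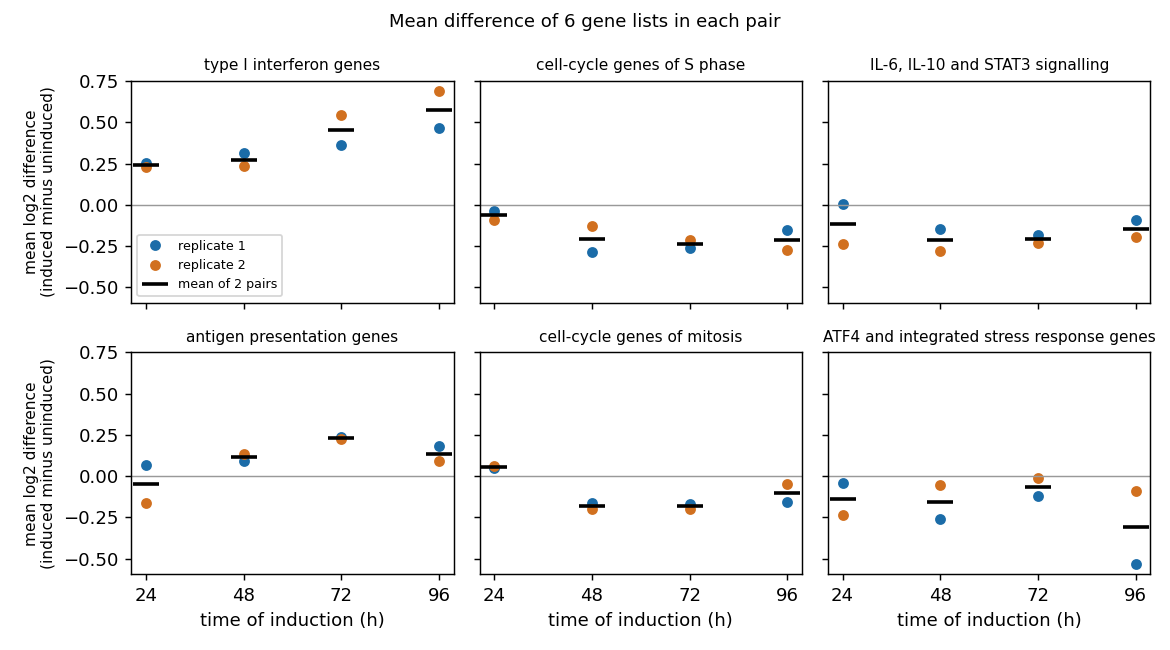
Mean log2 difference, induced minus uninduced in the direction of the bead files, of the 6 gene lists past the threshold, by time of induction in hours; points are single pairs coloured by replicate and black bars are means of 2 pairs. The interferon mean runs from 0.24 at 24 h to 0.58 at 96 h, and the mitosis mean is 0.06 at 24 h and below 0 at the other times; with the columns as named, every sign turns.

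Markers of cell types that a B-cell culture should lack did not pass as lists. This tests their difference with induction and not whether such cells were absent. These lists held 12 genes each, and those without a named probe above the filter on dim probes were not tested. Among the tested markers, uninduced signal was well above the array medians for some, such as EPCAM with 10.13 and CD68 with 9.58. For others it was near them. T-cell markers had a mean of 0.01 (6 measured, camera adjusted p = 0.934), with a median of -0.002, and myeloid markers -0.04 (5 measured, 0.768). Fibroblast and epithelial markers had a mean of 0.12 (7 measured, 0.161); of these COL1A2 passed over the list alone, differing by 0.45 at an uninduced signal of 4.80, below the array medians.

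The third comparison asked about each time of induction on its own. By the bead-file direction, limma called 0 genes at 24, 48, 72 and 96 h. At an unadjusted p under 0.05 there were 1068 genes at 24 h, 778 at 48 h, 873 at 72 h and 1185 at 96 h. Chance alone puts a share of 0.05 of the 12463 genes under that p, so much of each count needs no effect. The smallest adjusted p at these times was 0.537, 0.203, 0.276 and 0.15. In simulated data with these means and spreads, where genes changed by at most 1 on the log2 scale, 0% of the changes of 1 were recovered at 24, 48 and 96 h and 1% at 72 h. A second simulation also held changes of 2 and recovered 86.67% to 91.67% of them and 33.33% to 43.33% of the changes of 1. A change of 1 at a single time was thus mostly not detectable with 2 pairs. An intensity trend in the variance gave 7 genes at 72 h and 14 at 96 h, the upper 25% of probes 12 at each, and the bead files 29 and 70 codes. By size alone, the difference of RSAD2 was 0.24 at 24 h, 1.04 at 48 h, 1.215 at 72 h and 1.58 at 96 h. That of SOCS3 was -1.10, -0.66, -1.72 and -1.355, and that of BCL3 was -0.43, -0.46, -0.67 and -0.77.

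A linear trend of the effect with time was then tested for each gene. Limma called 0 genes, with 699 at an unadjusted p under 0.05 and a smallest adjusted p of 0.299. An F test of any difference between the times also called 0, with 753 genes at an unadjusted p under 0.05. Chance alone puts a share of 0.05 of the 12463 genes under that p, which is most of the 699 and of the 753. The trend count was 0 in all 24 alternatives run. In the 2 simulations the trend test recovered 68% and 72.5% of genes whose effect changed by 0.5 per day. The gene with the smallest p was KIF1C, a kinesin, chosen after its value was seen, with a slope of 0.54 per day.

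The last comparison followed the uninduced cells over time, as the background for the induced ones. Which 8 arrays are uninduced rests on the bead-file direction, so with the columns as named the counts, slopes and genes of this comparison come from the other 8 arrays. Limma called 0 genes with a linear trend over the 8 uninduced arrays, with 731 at an unadjusted p under 0.05 and a smallest adjusted p of 0.727. Chance alone gives most of the 731. Without the uninduced array of replicate 2 at 72 h, 1 gene passed: TM6SF1, a membrane protein, with a slope of 0.81 per day (adjusted p = 0.0482, against 0.817 with all 8 arrays). With the columns as named limma also called 0 genes. ATF4 pathway genes had slopes of 0.28 per day in replicate 1 and 0.20 in replicate 2. In the induced arrays the same list had slopes of 0.15 and 0.25, which are the values of uninduced cells if the columns are taken as named. These slopes were not tested. In replicate 2 the times were spread over several BeadChips, so a slope there may reflect the BeadChip. The replicate number as a block does not remove this from the trend test.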

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

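Of the tests given in the paragraphs that follow, those of the column direction and of the NFKBIZ bead code and the count of arrays without the NFKBIZ hairpin were chosen only after the results were seen.

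For 5 of the 24 lists, both pairs at one time lay above 0 and both pairs at another time below, where chance alone gives 10.3 of 24. The difference between those 2 times was not tested. Mitosis genes had a mean difference of 0.06 at 24 h and -0.18 at 72 h, a gap of 0.24, and their trend over the times had an exact permutation p of 0.175. Myeloid markers had a gap of 0.475 between 48 and 72 h, and T-cell markers of 0.213 between 96 and 24 h. Immediate early genes had a gap of 0.20 between 72 and 96 h, and B-cell receptor signalling genes of 0.144 between 72 and 24 h.

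NFKBIZ, the target of the hairpin, was higher in the value-table columns named induced. Within-pair differences of the table correlated with those of the bead files by -0.871 or less in all 8 pairs, as an exchange of columns needs. A rise of NFKBIZ in the scanned arrays labelled induced is argued against by the matched bead code, which differed by -0.423 (SE 0.078) and was lower in 8 of 8 pairs. A candidate explanation is therefore that the columns were named the wrong way round within pairs. That the labels of the bead files were exchanged instead stays open, since both sets of labels come from the submitters and no other set was analysed here.

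Type I interferon genes were higher in the induced arrays, and 1 of 100 splits that exchange arrays within pairs, the real one, gave a list mean as large (0.386, highest other 0.329). With 8 of 8 pairs higher this count repeats the exact permutation test (adjusted over 24 lists 0.0375) and excludes chance no further than that test does. The authors' normalization is argued against, since bead intensities normalized afresh gave a median of 0.417 over 24 matched members, against 0.383 in the table. A gradient along the sections of a BeadChip needs the list mean to step up again from an induced array to the next section; 3 of 4 such steps went down (-0.45, -0.47 and a nearly flat -0.03) and 1 went up by 0.16, so it cannot be told apart from induction by the bound set beforehand, which was 4 steps down. A response to any induced hairpin, or to doxycycline, could also account for the rise, with 0 arrays without the NFKBIZ hairpin to set against it, and an effect of lower NFKBIZ stays open beside these.

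S-phase genes were lower in the induced arrays, and 1 of 100 such splits, the real one, gave a list mean as large in size (0.181, highest other 0.157). With 8 of 8 pairs lower this too repeats the exact permutation test (adjusted over 24 lists 0.0375) and excludes chance no further. A shift that depends on signal intensity is argued against, since the list median lay at percentile 0 of 10000 random lists matched on mean signal. A gradient along the sections needs further steps down; 3 of 4 steps went up (0.55, 0.40 and 0.15) and 1 went by -0.24, so by the bound of 4 it cannot be told apart from induction. In the bead-file direction, slower growth of cells with less NFKBIZ is 1 hypothesis for the difference, but growth was not measured here. A response to any induced hairpin, or to doxycycline, could account for it as well. There were 0 arrays without the NFKBIZ hairpin to tell these apart.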

How the results depend on the processing

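Taking the columns as named, quantile normalization of the table, removal of a loess trend from each pair and the matched bead codes were chosen after seeing the data; the other alternatives were fixed before. The 17 genes over all times became 44 with no filter on dim probes, 156 with the upper 25% of probes, 35 with the BeadChip as block, 190 with an intensity trend, 40 with array weights, 6 at an adjusted p under 0.01, 587 codes from the bead files, and 27 after quantile normalization and 27 after the loess. Quantile normalization and the loess kept all 17 genes, and subtraction of array medians 15. Without the replicate block the count was 0, and 9 lists passed in place of 6. Leaving out pairs or a replicate gave 0 to 23 genes, and 3 to 9 of all 24 lists in place of 6. The cause of these moves was not tested, except that a stricter threshold makes fewer calls by construction.

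At 72 and 96 h the count of 0 became 12 and 12 with the upper 25% of probes, 7 and 14 with an intensity trend, and 29 and 70 codes with the bead files; it stayed 0 at 24 and 48 h and for the time trend in all alternatives run. In uninduced cells leaving out each array gave 0 to 1 gene. NFKBIZ kept its direction except with the columns as named (0.456), and passed the threshold with the upper 25% of probes (-0.456, adjusted p = 0.0104), an intensity trend (-0.456, 0.00415), array weights (-0.469, 0.0334) and the matched bead codes (-0.423, 0.00255). Its adjusted p ran from 0.00255 to 0.525, and without pairs or a replicate its difference from -0.509 to -0.402.

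With an estimated correlation 0 lists passed, at list means of 0.386 for interferon (adjusted p = 0.101), -0.181 for S phase (0.101), -0.103 for mitosis (0.306), -0.171 for IL-6, IL-10 and STAT3 (0.151), -0.167 for ATF4 (0.306) and 0.109 for antigen presentation (0.356). With fry the mitosis list (-0.103, 0.0687), the ATF4 list (-0.167, 0.0687) and the antigen presentation list (0.109, 0.131) did not pass, while 3 others did: ABC markers (0.00306), NF-kB subunits and IkB family (0.0089) and MYC and ribosome biogenesis (0.0089). Antigen presentation also missed the threshold in the upper 25% of probes (0.083, 0.0514). With the columns as named the list means were -0.386 for interferon, 0.181 for S phase, 0.103 for mitosis, 0.171 for IL-6, IL-10 and STAT3, 0.167 for ATF4 and -0.109 for antigen presentation. Leaving out pairs or a replicate gave -0.236 to -0.106 for IL-6, IL-10 and STAT3, -0.126 to -0.089 for mitosis, -0.238 to -0.096 for ATF4 and 0.074 to 0.148 for antigen presentation, with no change of sign. Interferon and S phase lost their call only with the estimated correlation among the alternatives run.

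The 17 genes past the threshold gave 340 values under the alternatives, all in their first direction, the columns as named not counted; 105 of them missed the threshold, 17 without the block and 82 with pairs or a replicate left out. No normalization equals the main setting, since the table was used as deposited. Normexp and the median of beads were not run, as the table is on the log2 scale and the main values were taken from it. A robust variance does not enter camera. Bead codes have no names of their own, so list and NFKBIZ values from them were had only through the match by pair means. Where 1 pair of a time is left out, the lone pair is assumed to vary like those of the other times. Genes near the array medians of 5.02 to 5.07 are limited by signal over background.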

Other observations

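The test of doxycycline through ATF4 target genes was chosen only after the result was seen. Several lists of metabolism and early response did not pass as groups but held single genes past the threshold over the list alone, here in the direction of the bead files. Of 25 hypoxia and glycolysis genes 1 passed in this way: ADM, a secreted peptide induced by low oxygen, differed by 0.71 (SE 0.14, adjusted p over all genes 0.0628) and was higher in 8 of 8 pairs. The list mean was 0.01 and its median -0.02, and the glycolytic enzyme PGAM1 differed by -0.33 and was lower in 8 of 8 pairs (camera adjusted p of the list 0.973). Among 17 cholesterol synthesis genes SC5D, a sterol desaturase, differed by 0.41 and was higher in 8 of 8 pairs (list mean 0.05, camera adjusted p = 0.223). Of 19 immediate early genes 4 passed over the list alone. EGR1 and EGR3, transcription factors induced by receptor signals, differed by 0.52 and 0.49, EGR3 from a signal of 5.03 near the array medians, whereas MYC and ATF3 differed by -0.30 and -0.31 (list mean 0.004, median -0.02, camera direction down, adjusted p = 0.934).

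Lists of organelles and of cell death did not pass in camera either. Unfolded protein response genes had a mean of -0.08 and were lower in 7 of 8 pairs (17 measured, camera adjusted p = 0.137, fry 0.0933), though the exact permutation test of the mean gave 0.0156 (adjusted over 24 lists 0.0468); the chaperone HSPA5 differed by -0.28 and the disulfide isomerase PDIA4 by -0.27. Mitochondrial ribosome and respiratory chain genes had a mean of -0.05 (26 measured, 0.178), with NDUFS3 at -0.175 and MRPS7 at -0.20. Their trend over the times was -0.05 per day (exact permutation p = 0.0135, adjusted over 24 lists 0.162). For p53 target genes the mean was 0.04 (20 measured, 0.505), and POLH differed by -0.38 and SESN1 by 0.34. BCL2 family genes had a mean of 0.01 and a median of -0.002 (16 measured, 0.934), with BAD at -0.25 and BCL2 at 0.16. No member of these 4 lists passed, over all genes or over its list alone.

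Doxycycline slows protein synthesis in mitochondria, which could raise ATF4 target genes in induced cells without any role of NFKBIZ. In the bead-file direction the list mean was -0.167 (SE 0.061), lower in 8 of 8 pairs, the opposite of such a rise. That is the fall which prompted the test, so it decides nothing further. The list also missed the threshold in camera with an estimated correlation (adjusted p = 0.306) and in fry (adjusted p = 0.0687). With the columns as named the mean is 0.167, in the direction of such a rise, so an effect of doxycycline on these genes stays open.

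Exchanging arrays within pairs gave 17 genes in the real arrangement and at most 1 in the others. Thus 1 of 100 splits, the real one, reached the count. This argues against chance but does not exclude it, since the smallest exact p that 8 pairs allow is 0.00781. Without the pair as a block the count was 0. For the number of lists, 2 of 100 splits gave as many as the real 6, and the other had 8 and exchanged 1 of the 8 pairs. Of the 99 other splits 66 called at least 1 list, with a median of 1, and those that exchange few pairs keep most of the real difference. Among the 28 splits that exchange 4 pairs 13 called 1 list and none called more, so a single list past camera's preset correlation is weak evidence, while 6 are more than these splits gave.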
